A study of Homo sapiens with 4 samples.

How the data were processed

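The series holds 4 Affymetrix Human Gene 1.0 ST arrays of MRC-5 cells, 2 from vehicle-treated and 2 from SWCNT-treated cells, with the groups and replicate numbers taken from the sample titles. The labels' protocols describe total RNA reverse transcribed and converted through cRNA to single-stranded DNA, with biotin as the label. The submitters' processing notes name GCOS, Affymetrix Expression Console and RMA, without versions or settings. The authors deposited log2 values per probe set, 1 column per array. That the scale is log2 follows from RMA in the notes and from the values themselves, which run from -0.379 to 13.7 with nearly equal quantiles on the arrays. No scanner files were used here, so background correction, layout and annotation files, and the genome build, are not given in the sources used here. RMA as generally run brings arrays to a common distribution, and a change of all genes together would then not show in these values. The number of arrays limits the precision.

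Probe sets were named through GEO's platform annotation and the RefSeq gene table of GRCh38.p14. Of 33297 rows 19460 had 1 gene symbol, 1754 had several and were left unnamed, and 12083 were not listed. The gene number of 19429 rows matched the RefSeq table, and 0 symbols needed an update. For each of 18417 genes the probe set with the highest mean over the 4 arrays was kept, which mattered for 769 genes with several. The 40% of genes with the lowest mean over all arrays were left out, leaving 11050 tested genes with a mean above 0.543. Entries of the fixed gene lists were matched through current symbols and synonyms, and 1081 of 1172 were on the array.

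Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, group as the only term, Benjamini-Hochberg adjusted p under 0.05). Gene lists with at least 5 tested genes were compared with camera at a preset correlation of 0.01, and also with an estimated correlation and with fry. An exact permutation test of 2 against 2 cannot go below 0.333 (two-sided), so single values were not tested that way. Shares of genes above the background limit were compared with one-sided Fisher's exact tests in scipy 1.17.1, with intervals by the exact Clopper-Pearson method at 95%. The olfactory receptor limit was chosen after seeing that most values lay near a floor.

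The rule for named genes, fixed before the data were examined, took the 12 largest called changes in each direction with non-overlapping groups, or the 6 smallest p per direction where none was called, and up to 4 members with the smallest p per described list. Small RNA genes, LOC and open reading frame names, and sex-specific genes were left out of the first part. Genes named for their level, and the 10 lists described gene by gene, were chosen after the levels were seen. The fits were checked on data simulated over the 11050 tested genes in 20 draws, and 0.0585% of unchanged genes were called. In the list test a list of 30 genes shifted 1.25-fold was called in 100% of draws and unshifted lists in 0 of 400 cases. Those simulated genes vary independently, which real genes need not. Most real lists were smaller than the simulated ones, with 5 to 36 tested genes, and were adjusted over 41 lists, more than in each draw. The share of 100% therefore does not carry over to the smaller lists.

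Alternatives changed the dim-gene filter, the probe set rule, the normalization, the prior, the replicate block, the threshold and the list test, and left out each array in turn. Restricting the test to genes above the background limit, leaving out probe sets off their gene's chromosome, and the other background limit were added after seeing the data. A probe set was called off its gene's chromosome where at least 60% of its 20 neighbours by number, 10 on each side, belonged to another chromosome. This used chromosome names of RefSeq genes and no coordinates.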

Results

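Gene expression was measured on 4 microarrays of MRC-5 cells, a fibroblast line from human embryonic lung. The cells had been kept for 72 h with pristine single-walled carbon nanotubes (SWCNTs, hollow cylinders with a wall of carbon) of regular length at 100 ug/mL, or with the PBS vehicle. Each group held 2 arrays, so the design asks which genes differ in level between nanotube-exposed and vehicle-exposed fibroblasts. The labels do not say whether the 2 arrays of a group came from separate cultures, and p-values therefore measure only the spread between these arrays, which may be technical. The 33297 probe sets on each array had a median log2 signal between 0.558 and 0.58, and the 99th percentile lay between 2.88 and 3.24.

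Most genes lay near the level of genes that fibroblasts are not known to use. The median gene had a log2 signal of 0.578, against 0.501 for 338 olfactory receptor genes, which encode odorant receptors of the nose. The 99th percentile of the olfactory receptors, a log2 signal of 0.82, served as a background limit. Of 18079 other genes, 1950 (10.8%) lay above it, and 26 genes of the whole table had a mean above 3. With the 95th percentile as the limit, 4229 genes (23.4%) lay above it. VIM, the intermediate filament protein vimentin, had a signal of 0.63 on both vehicle arrays and 0.638 ± 0.0617 in the SWCNT group (SD, n = 2). COL1A1, a chain of type I collagen, had 0.691 ± 0.171 and 0.909 ± 0.14. FN1, encoding fibronectin, had 0.564 ± 0.132 and 0.436 ± 0.00685. SPARC, a matrix glycoprotein, had 0.493 ± 0.0607 and 0.468 ± 0.0504. For comparison, ALB, the liver's serum albumin, had 0.528 on both vehicle arrays and 0.587 ± 0.0525. SFTPC, the surfactant protein of alveolar epithelium, had 0.628 ± 0.359 and 0.591 ± 0.0602.

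Among the 41 gene lists fixed before the data were examined, only the cytosolic ribosomal proteins passed a test for a larger share of genes above the background limit than among the other genes. In that list 19 of 40 measured genes (47.5%) passed the limit (one-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 2.22e-07). RPL5, RPL19 and RPS25 led it, with mean signals of 5.74, 4.51 and 4.47. The metallothionein and zinc transport list, small metal-binding proteins for the most part, had 5 of 11 genes above the limit, led by MT2A at 2.00 from a probe set off its chromosome and at 0.50 from the one on it, and did not pass (adjusted p = 0.0787, same test). Of the lung fibroblast identity genes 4 of 27 passed the limit, namely TWIST1, TWIST2, MEOX2 and TBX2. The collagens had 5 of 25 above it. Markers of other cell types stood at similar shares, with 5 of 21 for epithelium, 4 of 18 for endothelium, 2 of 20 for blood and macrophages and 2 of 15 for smooth muscle and pericytes. The shares of these 6 lists ran from 10% to 23.8%, and none passed the test for a larger share than among the other genes (adjusted p from 0.854 to 0.981, same test).

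**Figure D1:**
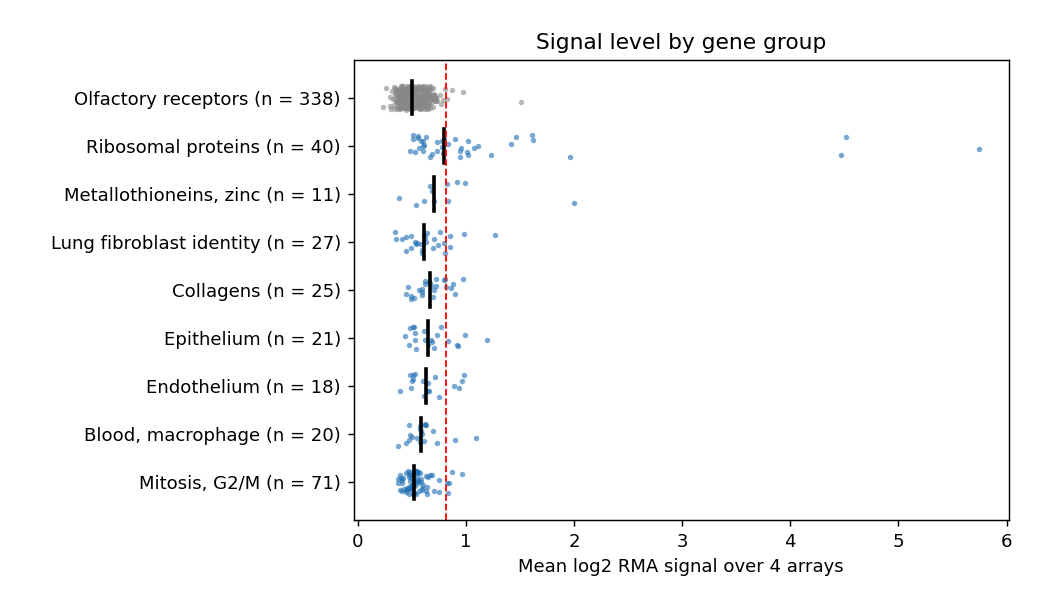
Mean log2 RMA signal over the 4 arrays (x axis) for genes of the olfactory receptor group and 8 of the fixed gene lists (y axis); each point is a gene, the black bar is the list's median and the dashed line is the background limit of 0.82. The lung fibroblast identity genes have a median of 0.61, close to the 0.648 of the epithelial markers, while ribosomal protein genes reach 5.74.

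A small set of named genes was bright on all 4 arrays. PTMA, encoding prothymosin alpha, had a signal of 6.33 ± 0.0152 with vehicle and 6.27 ± 0.129 with SWCNTs (SD, n = 2 each). HNRNPD, an RNA-binding protein of the hnRNP family, had a mean of 5.88 over the 4 arrays. YBX1, the Y-box RNA-binding protein, had 5.55 ± 0.154 and 5.71 ± 0.028. EEF1A1, the translation elongation factor, had 4.19 ± 0.376 and 4.02 ± 0.0839, and GAPDH, the glycolytic enzyme, had 3.61 ± 0.675 and 3.68 ± 0.0545. The probe sets behind PTMA, RPL5 and EEF1A1 stand, by their place in the probe set numbering, among probe sets of another chromosome than the gene's own. These genes were chosen after their values were seen. Of the 10 brightest probe sets, 3 were annotated to several ribosomal RNA loci and the other 7 had no annotation in the table used here.

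Arrays of one group resembled each other no more than arrays of different groups. Over the 11050 genes tested, Pearson's r across genes was 0.699 between the vehicle arrays and 0.738 between the SWCNT arrays, against 0.689 to 0.755 for the 4 pairs that crossed the groups. Spearman's rho over the same genes was lower, 0.274 and 0.345 within the groups and 0.281 to 0.398 between them. The ranks of these genes were thus only weakly reproduced from array to array. Between 3.38% and 3.62% of probe sets had identical values in each pair of arrays. Genes are not independent replicates, so these values describe the arrays only. The standard deviation of the log2 difference was 0.234 and 0.222 within the groups and 0.22 to 0.236 between them. Vehicle replicate 2 gave the lowest r with each of the other arrays.

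No gene was called higher or lower with SWCNTs. The limma test with Benjamini-Hochberg adjustment over 11050 genes gave 0 genes at an adjusted p under 0.05, and the smallest adjusted p was 0.951. At an unadjusted p under 0.05 there were 259 genes with a higher and 189 with a lower value in SWCNT cells, together 448, where chance alone gives 552.5. That balance rests on single arrays, as it was 157 higher and 332 lower without vehicle replicate 2 and 313 higher and 118 lower without SWCNT replicate 2. The arrays of the groups did not overlap for 3267 genes (29.6%), against 33.3% expected by chance for 2 against 2. A fitted difference of at least 2-fold was seen for 3 genes on the higher and 4 on the lower side, against 8 and 6 without vehicle replicate 1, 3 and 7 without vehicle replicate 2, and 7 and 2 with either one of the SWCNT arrays left out. The median 95% confidence interval of a log2 change was ± 0.308, equal to 1.24-fold either way. For the 1954 genes above the background limit, fitted alone, it was ± 0.407, equal to 1.33-fold. In simulated data that kept the genes' means, each gene's variance was drawn anew from the prior fitted over all tested genes, whatever its signal. There the test found 54% of genes changed 2-fold in signal, 90.4% of those changed 4-fold and 2.6% of those changed 1.5-fold. As the genes above the background limit had wider intervals, the shares may be lower for them. Genes changed 1.5-, 2-, 4- and 8-fold were mixed in each draw, 1000 of each over 20 draws. The adjustment ran over all of them together, so the share found may differ where 2-fold changes occur alone. These shares refer to a change in signal, and at the floor described above a change in RNA may not alter the signal by the same factor.

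**Figure D2:**
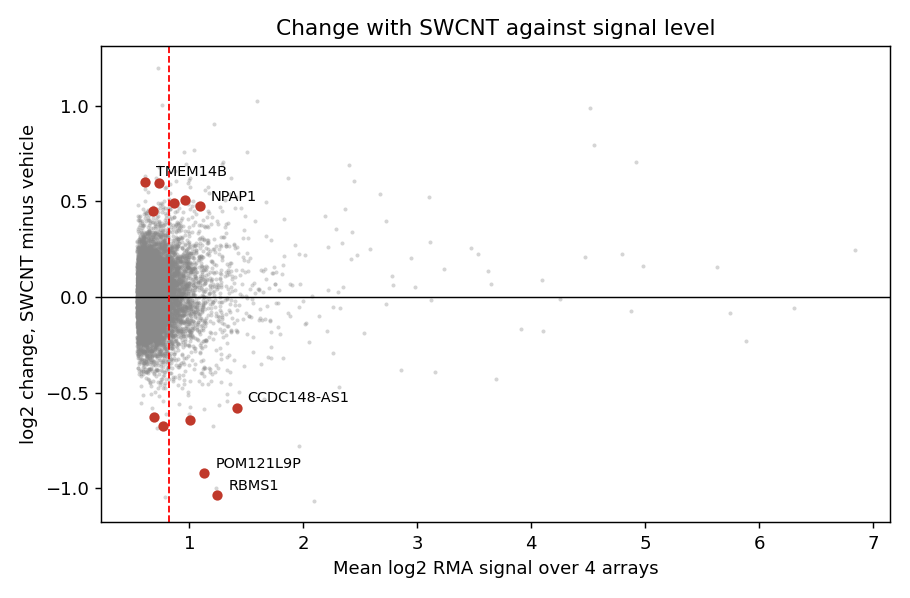
Fitted log2 change, SWCNT minus vehicle (y axis), against mean log2 RMA signal over the 4 arrays (x axis) for the 11050 genes tested; red points are the 6 genes with the smallest p in each direction, some of them labelled, and the dashed line is the background limit of 0.82. Most genes lie at low signal, and none of the points passes an adjusted p of 0.05.

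The genes with the smallest p on the higher side did not pass the test (limma adjusted p = 0.951 for each gene of this paragraph). TMEM14B, encoding a small membrane protein, had 0.308 ± 0.0152 with vehicle and 0.911 ± 0.0276 with SWCNTs (SD, n = 2 each), a log2 difference of 0.60 (95% interval 0.38 to 0.82). APOA5, an apolipoprotein of the liver, differed by 0.49 and NANOS2, a germ cell regulator, by 0.51. ERVW-1, an envelope gene of retroviral origin, differed by 0.60, NPAP1 by 0.47 and H3C7, a replication-dependent histone H3 gene, by 0.45. On the lower side POM121L9P, a pseudogene of a nuclear pore protein family, had 1.59 ± 0.0553 with vehicle and 0.673 ± 0.0644 with SWCNTs, a log2 difference of -0.92 (95% interval -1.16 to -0.68). RBMS1, an RNA-binding protein gene, had 1.76 ± 0.178 and 0.729 ± 0.197, a difference of -1.03, but -0.44 when all of its probe sets were averaged. TIMM8A, a mitochondrial import chaperone, differed by -0.63, SYNGR4 by -0.64, TSBP1-AS1 by -0.67 and CCDC148-AS1 by -0.58.

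**Figure D3:**
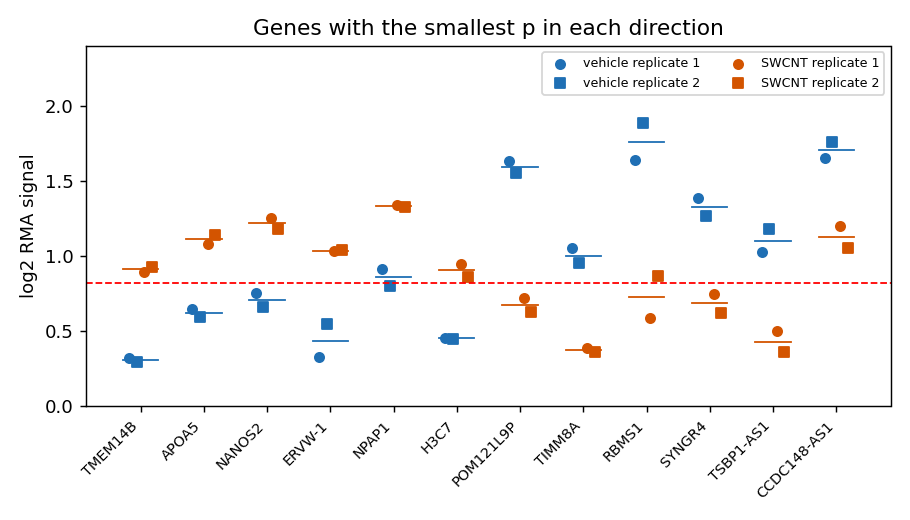
log2 RMA signal (y axis) of the 6 genes with the smallest p on the higher side and the 6 on the lower side (x axis); points are single arrays, short lines are group means (n = 2) and the dashed line is the background limit of 0.82. The 12 genes were picked by p, and their groups do not overlap, as for 29.6% of all genes tested. None of the 12 has an adjusted p under 0.05.

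None of the 41 gene lists was called. With limma's camera and a preset correlation 0 lists were called in either direction at an adjusted p under 0.05, and 2 lists had an unadjusted p under 0.05. With an estimated correlation, 0 lists had an unadjusted p under 0.05, and limma's fry gave 0 calls with 1 such list, the p53 targets. No member of any list passed the test, whether adjusted over all genes or adjusted over the list alone. List medians of the log2 difference ran from -0.08 to 0.11. The mean difference of 24 of the 41 lists turned sign when 1 of the 4 arrays was left out, and that of 12 did so without vehicle replicate 2. The median, the mean and the direction of the test differed in sign for 4 lists, namely S phase and DNA replication, metallothioneins and zinc transport, endocytosis and phagocytosis, and the epithelial markers.

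Collagen processing and crosslinking, the enzymes and chaperones that modify and link collagen, had the smallest p of the lists (camera p = 0.0112, adjusted p = 0.458, and adjusted p = 0.903 with an estimated correlation). Its mean signal was 0.628 ± 0.0192 with vehicle and 0.744 ± 0.0257 with SWCNTs (SD, n = 2 each), and 14 of its 16 tested members had the higher value in SWCNT cells. BMP1, the procollagen C-proteinase, differed by 0.62 in log2 (95% interval -0.06 to 1.31), and by 0.27 without SWCNT replicate 1. In the same list CRTAP differed by 0.18, PCOLCE by 0.21 and P4HB, the beta subunit of prolyl 4-hydroxylase, by 0.15, with none past the test. Only 2 of the 16 genes lay above the background limit. Fatty acid synthesis and storage was the other list with a small p, on the lower side (camera p = 0.0312, adjusted p = 0.639, and adjusted p = 0.903 with an estimated correlation).

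Lists for stress responses to particles gave 0 called members of each. Of 14 tested p53 targets 7 had a higher and 7 a lower value (camera adjusted p = 0.805), with PHLDA3 at a log2 difference of 0.36, BBC3, a pro-apoptotic BCL-2 family gene, at 0.28, AEN at 0.18 and BAX at -0.18. The NRF2 and oxidative stress list split 7 to 5 (camera adjusted p = 0.805), with UGDH at 0.19 and ABCC1, an export pump, at 0.08. It split 9 to 3 without vehicle replicate 1 or without SWCNT replicate 2, and 5 to 7 without SWCNT replicate 1. UGDH was 0.11 without vehicle replicate 2 and ABCC1 0.02 without vehicle replicate 1. In the metallothionein and zinc transport list, 4 members had a higher and 5 a lower value, the median was -0.02 and the mean 0.07. That mean was 0.0009 without vehicle replicate 2, and 0.15 without vehicle replicate 1, where 6 members were higher and 3 lower. MT1E, a member of this list, had 0.588 ± 0.168 and 1.09 ± 0.0288 (SD, n = 2 each), with a limma adjusted p of 0.951. Inflammatory cytokines and NF-kB targets had 13 of 19 members on the higher side (adjusted p = 0.805), but 8 of 19 without vehicle replicate 2, where the mean difference went from 0.06 to -0.01. Among them the chemokine CXCL3 differed by 0.57 (95% interval -0.21 to 1.36), and by 0.23 without vehicle replicate 2. CSF3, a granulocyte growth factor, differed by 0.20, and by 0.10 without vehicle replicate 2. On the lower side CXCL1 differed by -0.17, and by -0.01 without vehicle replicate 1. The 6 tested inflammasome genes had a median of 0.07 and an adjusted p of 0.805, with 6 on the higher side, but 3 without vehicle replicate 2 or without SWCNT replicate 2. None of the 14 measured inflammasome genes lay above the background limit.

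Lists for growth, matrix and cell identity also held 0 called members. The mitosis and G2/M list had 20 of 29 members on the higher side with a median of 0.04 (camera adjusted p = 0.805), and 14 without SWCNT replicate 2. CDC20, an activator of the anaphase-promoting complex, differed by 0.26, CDCA5 by 0.28, TOP2A by 0.18 and CEP55, which acts in the separation of daughter cells, by -0.39. CDCA5 differed by 0.11 without vehicle replicate 1 and CEP55 by -0.22 without SWCNT replicate 1. Collagens had 12 on the higher and 7 on the lower side, and 9 and 10 without vehicle replicate 2. COL16A1 was at 0.27, COL1A1 at 0.22, COL1A2 at 0.10 and COL10A1 at -0.10, and COL1A1 at 0.10 without vehicle replicate 2. TGF-beta targets split 6 to 6. They had 9 on the higher and 3 on the lower side without vehicle replicate 1 or without SWCNT replicate 1, and 5 and 7 without vehicle replicate 2 or without SWCNT replicate 2. CDKN2B was at -0.22, TGFB1 at 0.23 and CCN2 at 0.18, and with 1 array left out as small as -0.08, 0.08 and 0.06. Ribosomal proteins, the list with the most signal, had 21 of 36 members on the higher side and a median of 0.02, and 13 of 36 and -0.08 without vehicle replicate 2, with RPL13 at 0.50, RPL14 at 0.30 and RPL35 at -0.44. Lung fibroblast identity genes had a median of 0.07 and the marker lists of the other cell types had medians of -0.03 for epithelium, -0.03 for endothelium, 0.01 for blood and macrophages and -0.06 for smooth muscle and pericytes, with a camera adjusted p of 0.805 or above in each. Without vehicle replicate 2 the fibroblast identity median was 0.01 and the epithelial one 0.03, and without SWCNT replicate 2 the epithelial one was 0.08.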

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

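The limma test called 0 genes under each alternative with an adjusted p: the dim-gene filter set to none, 20% or 60%, averaged probe sets, repeated quantile normalization, median centring, a trended and robust prior, and the replicate block. Nor was any called by limma after leaving out each array in turn, where the lone array of a group is assumed to vary like the other group, or in both gene sets restricted after seeing the data. Gene lists, run without the dim-gene filter, with repeated quantile normalization, the replicate block, an estimated correlation, fry, each array left out and both restricted sets, also gave 0 calls, with a smallest adjusted p of 0.204 to 0.903. They were not rerun under the other gene-level settings. With the replicate block the count was 0 higher and 0 lower, with 430 genes at an unadjusted p under 0.05. Deviations of same-numbered arrays correlated at 0.05 across genes, so the numbers are not taken to pair the arrays, though the split by replicate number below gave the most genes. An unadjusted p under 0.05 with a 1.5-fold change gave 13 genes higher and 9 lower, and 41 and 42 without vehicle replicate 1, 11 and 55 without vehicle replicate 2, 35 and 12 without SWCNT replicate 1, and 57 and 16 without SWCNT replicate 2. It gave 24 and 14 with repeated quantile normalization and 24 and 13 with centring. Centring brought the smallest adjusted p over all gene-level alternatives, 0.635. The 4 arrays were also split into pairs in the other 2 ways. Split by replicate number, vehicle 2 and SWCNT 2 against vehicle 1 and SWCNT 1, 636 genes had an unadjusted limma p under 0.05, where chance gives 552.5. The remaining split gave 479 and the real split 448. Genes with a difference of at least 2-fold numbered 1, 3 and 7 in the same order. These 3 splits are too few for a share under 0.05. The mean within-group Pearson correlation of arrays was 0.719, and 0.66 with averaged probe sets, 0.836 over genes above the background limit and 0.69 without probe sets off their gene's chromosome. It was not recomputed with arrays left out. The 60% filter removed TMEM14B of the 12 named genes, and the restriction to genes above the limit removed TMEM14B, ERVW-1, H3C7, TIMM8A and TSBP1-AS1. The groups of all 12 do not overlap, so leaving out an array cannot turn their direction. Over genes above the limit alone, 8 lists had enough genes for camera. The ribosomal protein share above background was 62.5% at the lower limit and 41% without off-chromosome probe sets, and its call held. Low signal limits the comparison of most genes here, since genes near the floor may carry little information on RNA level.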

Other observations

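The tests of gene families, of unlisted probe sets, of levels against the background limit, of probe sets off their chromosome and of the signal of vehicle replicate 2 were chosen after the values were seen. Beyond the fixed lists, gene families were compared by level over the 4 arrays. As they were picked after their values were seen, the adjusted p-values describe these families and are not an independent test. Of 9 families looked at, hnRNP genes, which package and process nuclear RNA, had 9 of 19 members above the background limit (one-sided Fisher's exact test, adjusted p = 0.000196), led by HNRNPD, HNRNPK and HNRNPM. Serine and arginine rich splicing factors had 5 of 12 (adjusted p = 0.0135), led by SRSF1, and 14-3-3 genes 3 of 6 (adjusted p = 0.0322). Genes of hair and skin barrier, the keratin-associated and late cornified envelope proteins, had 27 of 84 (adjusted p = 9.43e-07), led by LCE1D and LCE1F. That is 32.1%, against 10.8% of the genes outside the olfactory receptors. Passing the limit therefore does not by itself show that a gene is expressed in these cells. Forkhead transcription factor genes had 14 of 39 (adjusted p = 0.000137), led by FOXC2 and FOXE3, and HOX genes 7 of 27 (adjusted p = 0.0322). Proteasome subunits had 8 of 36 (adjusted p = 0.0449), eukaryotic initiation factors 9 of 49 (adjusted p = 0.0857) and keratins 2 of 48 (adjusted p = 0.972). Base composition of the probes was not tested, as no sequences were used.

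ACTB, encoding beta-actin and chosen like MRPL36 after its values were seen, had 2.36 ± 0.337 with vehicle and 1.57 ± 0.263 with SWCNTs (SD, n = 2 each), a log2 difference of -0.78 with a 95% interval of -1.37 to -0.19 and a limma adjusted p of 0.951. MRPL36, a mitochondrial ribosomal protein, had 4.56 ± 0.00506 and 5.27 ± 0.425. Of the 12083 probe sets that the annotation does not list, 749 had an unadjusted p under 0.05, where chance gives 604, and 0 passed the limma test after adjustment (smallest adjusted p = 0.654). They were fitted with all 33297 probe sets under 1 shared prior and varied more, with a median 95% interval of ± 0.384 against ± 0.324. Such a fit can give them more small p, so the excess is not taken as a sign of change. Over all probe sets 1427 had an unadjusted limma p under 0.05, where chance gives 1665.

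Most genes lie near the level of olfactory receptor genes, including genes that cultured fibroblasts are known to use heavily, and no biological explanation was tested because both groups share the pattern. Rows joined to the wrong genes throughout would leave ribosomal proteins no brighter than other genes. Yet 47.5% of them passed the background limit (95% interval 31.5 to 63.9), against 10.8% of the genes outside the olfactory receptors. Without probe sets off their gene's chromosome the share was 41%. The criterion was set after the level of this list was known, and it says nothing on a wrong join of a part of the rows. Ordinary fibroblast values shifted or rescaled stay open: 23 genes abundant in fibroblasts, listed after the levels were seen and 18 of them also in the fixed lists, should then have a median rank percentile over 80, and it was 68.3 (bootstrap 95% interval 49.8 to 82.3). A second criterion, tried only after that outcome, found 34.8% of them below the median gene (exact 95% interval 16.4 to 57.3) where at most 5% was set, and as the second of 2 tried, on genes near the floor, it is not taken to exclude rescaling. Too little labelled RNA is another candidate explanation, with 21.7% of the 23 genes above the limit (exact 95% interval 7.46 to 43.7). Among the genes outside the olfactory receptors that share was 10.8%. Degraded RNA, or a layout file wrong for a part of the probe sets, could give the same, and the summarised values cannot tell these apart. The ribosomal protein share argues against a layout file wrong for all probe sets, as it does against a wrong join of all rows.

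The brightest named probe sets often lie off their gene's chromosome. Of 40 probe sets with 1 gene symbol and a mean above 3, 11 stood among probe sets of another chromosome (27.5%), against 0.895% of the other probe sets with 1 gene symbol, and the 273 unlisted ones above 3 have no gene to compare, but these 11 come from 6 genes, with 4 of PTMA and 2 each of RPL5 and EEF1A1, and are not independent. PTMA read 6.3 from such a probe set and 0.546 from the probe set on its own chromosome, and RPL5 5.74 and 0.621. Over 130 genes with both kinds, the off-chromosome one was higher in 71, lower in 52 and equal in 7 (two-sided exact binomial p = 0.104 with equal levels left out). One candidate explanation is that probe sets at gene copies measure RNA of the parent gene, for which the parent's own probe set was above the limit in 3 of 5 genes, too few to decide.

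Vehicle replicate 2 correlates least with the other arrays. Among 61 genes with a mean over 2, it was lower than the mean of the other arrays in 46, with a median difference of -0.265 (bootstrap 95% interval -0.362 to -0.19), while the medians of the other arrays were 0.175, 0.0941 and 0.00635. A lower signal of bright transcripts on that array cannot account for its lower correlation over the dimmer genes. Over the 10989 tested genes with a mean of at most 2, the mean r of its pairs was lower than that of the other pairs by 0.0866 (bootstrap 95% interval 0.0701 to 0.103). That interval resamples genes, which are not independent replicates. No biological explanation was tested, since the other vehicle array had the same treatment. Without vehicle replicate 2 the limma test called 0 genes, with 157 higher and 332 lower at an unadjusted p under 0.05, against 259 and 189 with all 4 arrays.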
